A study of Mus musculus with 2 samples.

How the data were processed

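Cortical myeloid cells of male 5xFAD hemizygous mice, a transgenic amyloid model on a C57BL/6J background, were profiled by droplet-based single-cell RNA sequencing. Per the labels, cells in the singlet, SYTOX-negative, Ly6G-negative, CD45-positive, CD11b-positive gate were sorted from 3 mice and pooled into 1 library per group. The deposited values were raw UMI counts per gene and barcode, made with bcl2fastq and Cell Ranger on mm10 per the submitters' processing notes. The Cell Ranger version was 3.0.2 per the file headers. Each library held 2000 barcodes and 31053 genes. A table of the whole series held the same counts, with 0 differing values. Gene lists and markers were matched by symbol, and 3 list entries without a match are not analysed here. Coordinates were taken by Ensembl identifier from the GENCODE annotation of the same assembly.

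A barcode was kept as a cell with at least 200 detected genes and at most 10% of UMIs from mitochondrially encoded genes. Cells of both libraries were clustered together without batch integration in scanpy 1.11.5. UMIs were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 20 principal components, 15 neighbours and Leiden resolution 0.8 were used with seed 1. A cluster took a class name when at least 3 markers of that class were among its 10 leading genes by fold. Otherwise it was called microglia-like when the microglia markers were detected in 50% of its cells on average. A microglia-like cluster was called disease-associated-like or homeostatic-like when the median log2 fold of those markers against other microglia-like cells exceeded 0.5, and otherwise its state stayed unnamed. The markers were fixed before the data were examined, and these naming thresholds were set afterwards. Because marker genes helped to define the clusters, states were also clustered without 110 marker and list genes, an alternative chosen after seeing the data. The resulting clusters were still named with the same markers. Values within states come from that clustering, because class II genes were among those that set the planned clusters. H2-Eb1 and H2-Ab1, though left out of that clustering, were still among the 10 leading genes of 1 of its clusters, in the unnamed state, so states of either clustering differed in class II level. Values within planned states are given as alternatives. Doublets were not removed in the main results. Scrublet called 28 of 555 and 5 of 317 cells with the fixed seed, and 23 and 19 cells with another seed, so its calls were unstable.

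Raw UMIs were summed over the microglia-like cells of each library and scaled to their total to give CPM. Sums carry exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95% and covering counting error only. Intervals of share differences combine the exact limits of both shares. With 1 library per group there was no replicate check, so no test, p-value or count of changed genes was made. A gene list was summarised by the median log2 CPM ratio of members with at least 20 UMIs, with 0.5 counts added to each sum, where at least 3 members were measured. The median was placed as a percentile among 10000 random lists of the same size matched in 20 expression bins, and its interval came from 2000 Poisson draws. Genes were named by a rule of size fixed before the data were examined. It took the 12 largest and 12 smallest ratios among genes with at least 100 UMIs, excluding mitochondrial, ribosomal, predicted and pseudogene symbols. It also took up to 4 members of each list, the 2 most abundant and the 2 with the most extreme ratio, and 10 genes given in every case, of which 9 are analysed here. Of the 102 genes so chosen, those that carry each comparison are described and the rest are summarised by list. The values of 1 of these genes are not reported here.

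To compare cells at equal depth, each was thinned to 1000 UMIs, the largest planned number reached by at least 80% of microglia-like cells of each library. This left out 99 control and 35 photoconversion cells. The ratio, interval and list steps were tested on simulated data before use. With 200 of 4009 genes changed by known folds between libraries of these depths, median recovered folds were 1.49, 1.95 and 2.94 for true folds of 1.5, 2 and 3. The intervals held the true fold for 95.8%, 97.0% and 93.7% of those genes. The simulated sums were Poisson draws, which the intervals assume, so such coverage was set in advance and checks the calculation only. UMIs concentrated in few cells were not simulated. Of 300 lists of 20 unchanged genes, 6% lay outside the central 95% of random lists. These lists were themselves random draws from the simulated genes, so a share of about that size was set in advance too. Lists whose members vary together were not simulated, so this check does not calibrate the percentiles of the lists used here. Alternatives covered the filters, scaling (including edgeR 4.0.16 TMM factors in R 4.3.3), equal weight per cell, thinning, all kept cells, doublet removal, added counts, list minimums and clustering settings. Added after seeing the data were leaving out the cells richest in a gene or list, values within states, equal state weights, the other doublet seed and clustering without marker genes. The share of a cell's UMIs from class II genes and the choice of leading lists were also made after seeing the data. Background barcodes were those with fewer than 100 detected genes.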

Results

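The series asked how ablation of meningeal lymphatic vessels bears on cortical microglia in an amyloid model. Mice aged 4 months received 5 uL Visudyne, a photosensitiser, into the cisterna magna, either alone or followed by 5 steps of transcranial photoconversion with 689-nm red light. The procedure was repeated after 3 weeks and tissue was taken 3 weeks later. There was 1 library per group, each from 3 pooled mice. The control library held 2672902 UMIs and the photoconversion library 2038693. Most barcodes were shallow, with a median of 120 UMIs in the control and 66 in the photoconversion library. The filters kept 555 control cells with a median of 2670 UMIs and 922 genes, and 317 photoconversion cells with a median of 3410 UMIs and 1120 genes. There was no replicate check, so every difference is one between these libraries, and intervals cover counting error only.

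**Figure D1:**
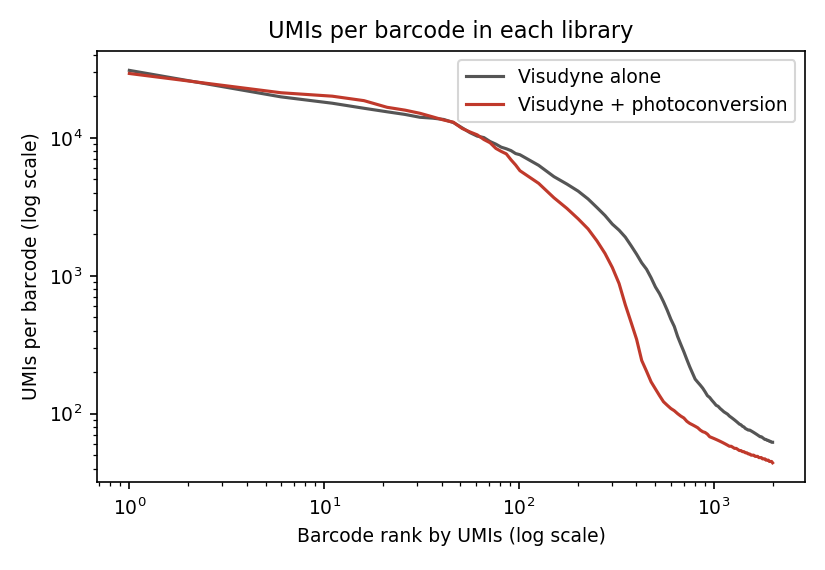
UMIs per barcode against barcode rank, both on log scales, for the 2000 barcodes of each library. The lowest barcode listed held 62 UMIs in the control and 44 in the photoconversion library.

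Microglia-like cells made up 515 of 555 kept cells in the control (92.8%, 90.3 to 94.8%) and 296 of 317 after photoconversion (93.4%, 90.1 to 95.9%). When cells were clustered without marker genes, disease-associated-like microglia were 69 of 491 microglia-like cells in the control (14.1%, 11.1 to 17.4%). They were 69 of 273 after photoconversion (25.3%, 20.2 to 30.9%), a difference of 11.2 percentage points (5.14 to 17.5). Homeostatic-like microglia were 54.0% of control cells (49.4 to 58.4%) and 45.4% of photoconversion cells (39.4 to 51.5%). In the planned clustering on all genes the disease-associated-like share was 26.2% in the control (22.5 to 30.2%) and 36.1% after photoconversion (30.7 to 41.9%). The homeostatic-like share there was 50.1% (45.7 to 54.5%) and 38.9% (33.3 to 44.7%). Most of that difference lay in a shallow cluster with a median of 1398 UMIs, 4.69% mitochondrial UMIs and Malat1 at 48646 CPM, which held 29.5% of control and 21.6% of photoconversion cells. The deeper homeostatic-like cluster, with a median of 4369 UMIs, differed by -3.35 points (-8.93 to 2.53). The unnamed planned cluster had Malat1, a nuclear RNA, at 183 CPM. The remaining microglia-like cells stayed unnamed, 32.0% of control (27.9 to 36.3%) and 29.3% of photoconversion cells (24.0 to 35.1%) without marker genes, and 23.7% and 25% in the planned clustering. Disease-associated-like cells were deep, with a median of 13771 UMIs without marker genes, and kept photoconversion cells were deeper than control cells. After clustering on thinned cells the disease-associated-like shares were 24.1% and 28.3%, a difference of 4.16 points whose interval (-2.63 to 11.1) included 0. The homeostatic-like difference was then -6.15 points (-13.6 to 1.5), and -5.35 points (-12.8 to 2.22) with at least 400 genes per cell.

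**Figure D2:**
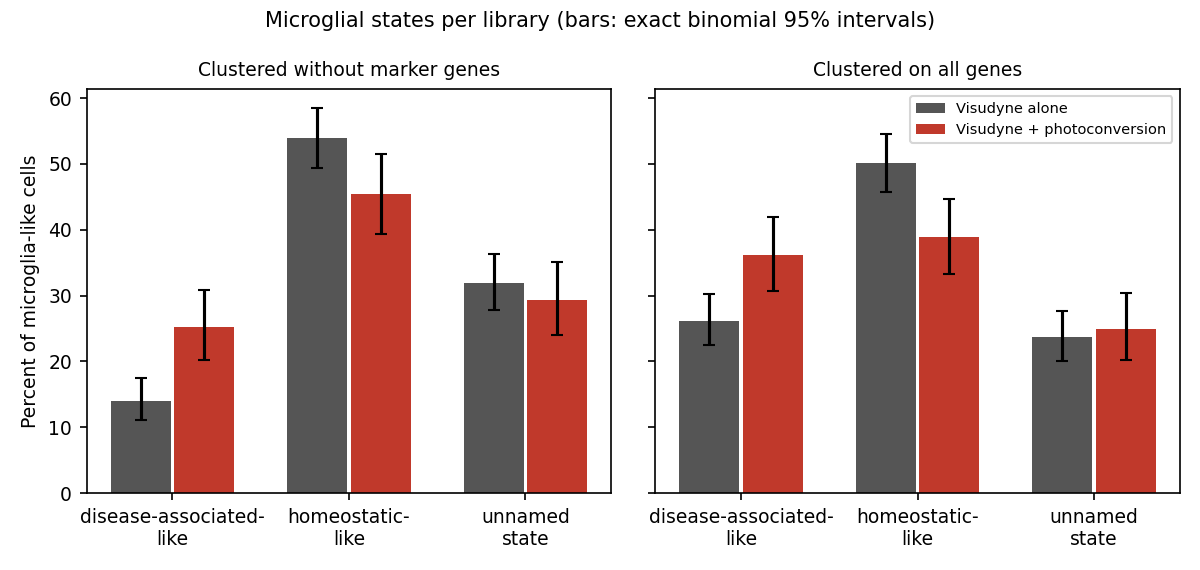
Percent of microglia-like cells in each state, per library, clustered without marker genes on the left and on all genes on the right; error bars show exact binomial 95% intervals. The disease-associated-like share was 14.1% and 25.3% on the left and 26.2% and 36.1% on the right for the control and photoconversion libraries.

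MHC class II antigen presentation genes had higher values after photoconversion. Cd74, the invariant chain (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652 in mm10), stood at 867 CPM in the control and 2521 CPM after photoconversion, a ratio of 2.91 (2.76 to 3.07). The class II chains H2-Aa, H2-Eb1 and H2-Ab1, all on chromosome 17, had ratios of 2.51 (2.29 to 2.75), 2.50 (2.24 to 2.81) and 2.43 (2.23 to 2.66). Few cells held most of these UMIs: without the 10 richest cells of each library H2-Aa had 77 of 727 control and 491 of 1391 photoconversion UMIs left, a ratio of 8.69 (6.82 to 11.2). H2-Eb1 then had a ratio of 6.57 (4.89 to 8.99), Cd74 3.87 (3.54 to 4.23) and H2-Ab1 2.73 (2.33 to 3.22). All 8 measured members of the list had values above 0, with a median log2 ratio of 1.30 (0.90 to 1.35), at percentile 100 among matched random lists. Of the peptide-loading members, named after their values were seen, H2-DMa was at 0.03, within the scaling shift of 0.03 to 0.05, and H2-DMb1 at 0.11. H2-Oa, with 263 UMIs in each library, was at 0.39, and H2-DMb2, with 16 and 32 UMIs, at 1.37. Within states clustered without marker genes, the list median was 1.43 in disease-associated-like cells, 3.18 in homeostatic-like cells and 0.07 in unnamed cells. In the planned states it was 0.93, 1.78 and 2.54, so the order of the states turned with the clustering. The Cd74 ratio was 3.21 (2.98 to 3.47) in disease-associated-like, 10.9 (8.86 to 13.5) in homeostatic-like and 1.47 (1.34 to 1.62) in unnamed cells of the clustering without marker genes. That clustering placed 53 control and 21 photoconversion cells of the planned disease-associated-like state among unnamed cells, with 2340 and 706 class II UMIs (6291 and 5482 CPM). The homeostatic-like value rested mostly on 17 photoconversion cells that the planned clustering called disease-associated-like, which held 1257 class II UMIs. In cells called homeostatic-like both ways, 248 in the control and 106 after photoconversion, class II genes had 555 and 449 UMIs and stood at 862 and 1339 CPM. The upper tail of cells differed more than the middle: class II genes took a median of 0.0827% and 0.114% of a cell's UMIs, and 0.281% and 0.879% at the 90th percentile. Thinned to 1000 UMIs, the median was 0.1% in both, which is 1 UMI per cell and too coarse to show a difference of that size in the median. The list median was 0.57 when cells were thinned and 0.64 when cells weighed equally. After thinning to 1000 UMIs, 17.3% of control (13.8 to 21.3%) and 31.4% of photoconversion microglia-like cells (25.8 to 37.4%) had a Cd74 UMI, against 32.6% and 52.7% unthinned. Endothelial-like cells, with median depths of 799 and 1309 UMIs against 2789 and 3647 in microglia-like cells, carried Cd74 too. Thinned to 500 UMIs, 4% of 25 control and 26.3% of 19 photoconversion endothelial-like cells had a Cd74 UMI, against 12.9% and 22.1% of microglia-like cells. The photoconversion shares with a Cd74 or H2-Ab1 UMI (12.6% against 15.8% for H2-Ab1) did not exceed this background, and those of H2-Aa (11.2% against 5.26%) and H2-Eb1 (9.12% against 5.26%) were higher. The control shares of H2-Aa (3.55% against 4%) and H2-Ab1 (6.68% against 8%) did not exceed it either. With 19 endothelial-like cells, whose name depended on the clustering, the background of such shares was set only loosely, so no difference is read from them.

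**Figure D3:**
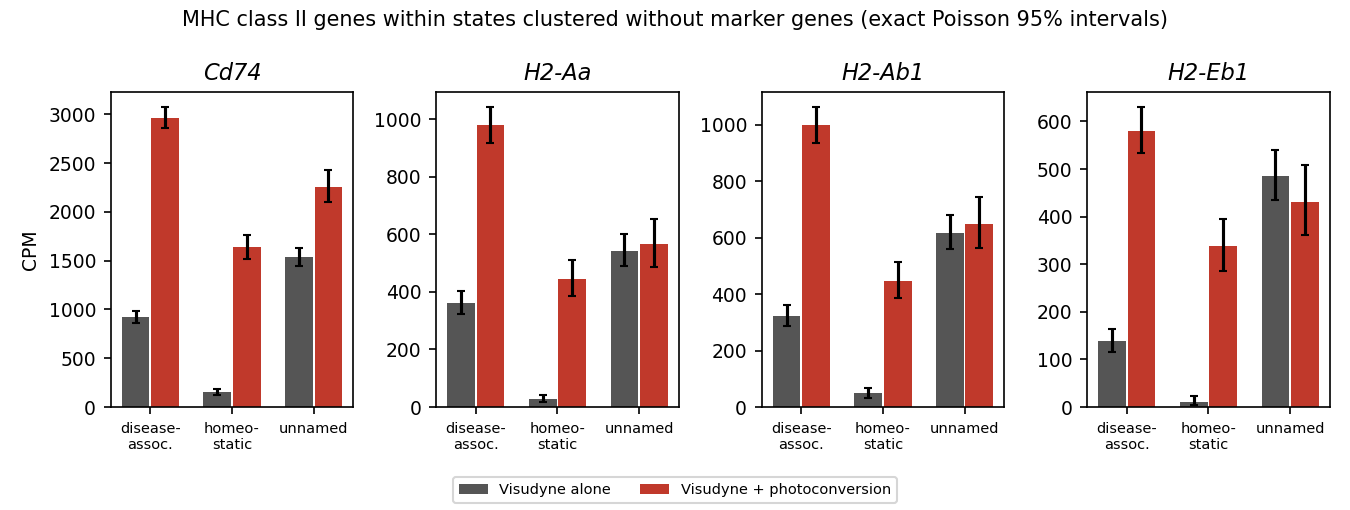
CPM of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 in disease-associated-like, homeostatic-like and unnamed microglia-like cells of each library, clustered without marker genes; error bars show exact Poisson 95% intervals. Cd74 stood at 922 and 2964 CPM in disease-associated-like cells of the control and photoconversion libraries, while H2-Aa stood at 542 and 566 CPM in unnamed cells.

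Homeostatic genes had lower values after photoconversion and early disease-associated genes slightly higher ones. Of 27 homeostatic members 24 were lower, with a median log2 ratio of -0.18 (-0.27 to -0.14) at percentile 0.02, and -0.31 with cells weighed equally. The purinergic receptor P2ry12 had a ratio of 0.813 (0.775 to 0.852), Tmem119 0.882 (0.820 to 0.948) and Txnip 0.588 (0.465 to 0.740). With equal weights of planned states Tmem119 turned to a log2 ratio of 0.14 and Trem2, a receptor of the disease-associated program, to -0.043. The fractalkine receptor Cx3cr1 had a ratio of 0.986 (0.932 to 1.04). Of the Trem2-independent stage of disease-associated microglia, 6 of 8 members were higher, with a median of 0.14 (0.12 to 0.16) at percentile 99.5, and 0.21 when cells were thinned or weighed equally. The lipid carrier Apoe stood at 8703 and 11376 CPM, a ratio of 1.31 (1.28 to 1.33). Of the Trem2-dependent stage, 6 of 10 were higher, with a median of 0.10 (0.01 to 0.21) at percentile 97.1, inside the central 95% of matched random lists. It was 0.0089 when cells were thinned and 0.37 when they weighed equally. Among the higher members of this stage, the ratios in the main sums were 1.18 (1.14 to 1.22) for Cst7, 1.30 (1.12 to 1.52) for Axl and 1.28 (1.06 to 1.54) for Itgax. They were 1.05 (1.02 to 1.08) for Trem2 and 1.09 (0.997 to 1.2) for Lpl. The 4 lower members had log2 ratios of -0.12 for Ctsl, -0.097 for Cd9, -0.020 for Ccl6 and -0.041 for Lilrb4a, the last with 15 and 11 UMIs. Other disease-associated genes had a median of 0.04 (-0.03 to 0.13) at percentile 90.8, with 11 of 19 higher. A cell's median share of UMIs from the disease-associated lists was 7.04% in the control and 8.15% after photoconversion, and 7.5% and 8.6% when thinned. For homeostatic genes it was 10.1% and 8.36%, and 9.75% and 8.4% when thinned. Within disease-associated-like cells clustered without marker genes the medians were -0.06 for homeostatic and 0.03 and -0.08 for Trem2-independent and Trem2-dependent genes. Of the Trem2-dependent members 7 of 10 were lower there. Other disease-associated genes had a median of -0.17 in these cells, with 15 of 19 lower. Within homeostatic-like cells the homeostatic median was -0.21, with 25 of 27 members lower, and with equal state weights it was -0.19. With planned states these values were smaller, -0.082 and -0.084.

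Type I interferon response genes had a median log2 ratio of 0.25 (0.10 to 0.45) at percentile 100, with 21 of 27 members higher. Their summed level was nearly equal, 2591 and 2649 CPM. Within states clustered without marker genes, the median was 0.46 in disease-associated-like cells with 16 of 24 members higher, 0.18 in homeostatic-like cells with 13 of 21 higher and -0.06 in unnamed cells with 7 of 16 higher. In planned homeostatic-like cells it was -0.63. The median was 0.27 with cells weighed equally, 0.078 when cells were thinned and -0.12 without the 10 richest cells of each library, which were 10 of 515 control and 10 of 296 photoconversion cells. A cell's median share from this list was 0.127% and 0.160%, and 0.100% in both when thinned. MHC class I genes had a median of 0.13 (0.10 to 0.26) at percentile 99.9, with 12 of 16 higher. The classical chain H2-D1 had a ratio of 1.43 (1.37 to 1.49) and H2-Q7 1.86 (1.49 to 2.34).

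Cytosolic ribosomal protein genes were higher in 78 of 80 members, with a median log2 ratio of 0.11 (0.10 to 0.13) at percentile 100. Rps20 had a ratio of 1.18 (1.13 to 1.23). A cell's median ribosomal share was 15.9% and 20.3%, and 18.0% and 20.9% when thinned. Heat shock genes had a median of -0.23 (-0.37 to -0.08) at percentile 1.32, with 6 of 8 lower, and Hspa8 a ratio of 0.680 (0.628 to 0.735). Immediate-early genes had a median of -0.20 (-0.28 to -0.01) at percentile 3.81 with 11 of 14 lower, and a cell's share of 0.0968% and 0.0867%, or 0.100% in both when thinned. Lysosomal genes had a median of -0.09 (-0.14 to -0.06) at percentile 2 with 26 of 35 lower. Glycolysis and hypoxia genes had a median of -0.12 (-0.17 to -0.02) at percentile 6.14 with 12 of 16 lower, which was 0.00069 when cells were thinned. Cell cycle genes had a median of -0.23 (-0.36 to 0.02) at percentile 2.65 with 14 of 21 lower. Immediate-early, glycolysis and cell cycle medians thus lay inside the central 95% of matched random lists. The remaining functional lists lay closer to 0, several of them within the 0.03 to 0.05 by which other scalings moved all values, and no direction is given for these. Their medians were 0.03 for lipid handling, 0.00 for cholesterol synthesis, -0.02 for complement, -0.02 for cytokines and chemokines, -0.07 for phagocytic receptors and -0.06 for antioxidant genes. They were -0.03 for nuclear-encoded oxidative phosphorylation, which turned positive under TMM and median-of-ratios scaling, 0.00 for mitochondrially encoded genes and -0.01 for Alzheimer risk gene orthologs. A cell's median mitochondrial share was 3.19% and 3.24%, and 3.20% in both when thinned, where shares move in steps of 0.100%.

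**Figure D4:**
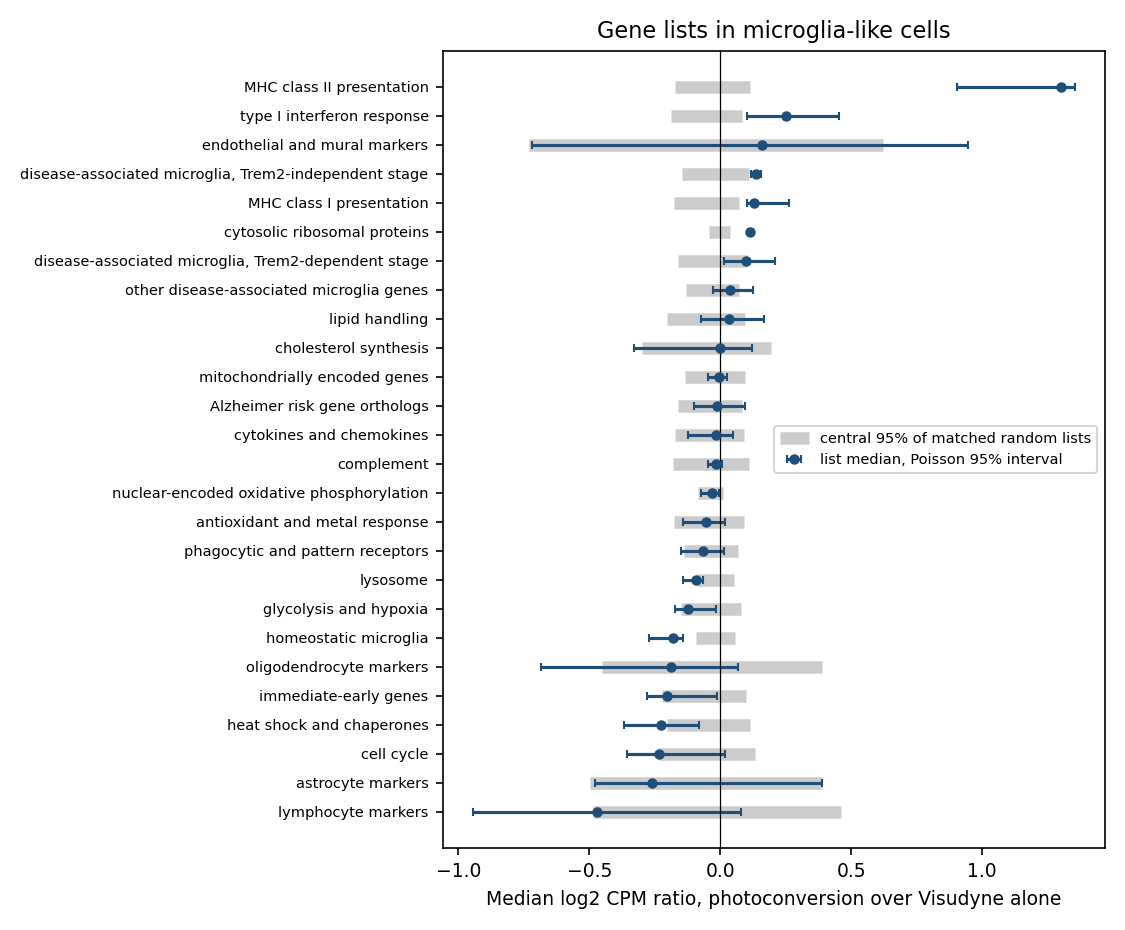
Median log2 CPM ratio of each gene list in microglia-like cells, photoconversion over Visudyne alone, with Poisson 95% intervals; grey bars span the central 95% of matched random lists. MHC class II presentation lies at 1.30 and homeostatic microglia at -0.18.

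The other genes with the largest ratios were often carried by few cells too. Cxcl10, an interferon-induced chemokine, had 13 and 254 UMIs, of which 217 were in a single photoconversion cell. Osteopontin, Spp1, had a ratio of 2.99 (2.63 to 3.41), and 1.08 without the 10 richest cells of each library. Cck had a ratio of 6.10 (3.86 to 10.0), and 1.68 without those cells. The histone gene Hist1h2ap had a ratio of 2.71 (2.12 to 3.49), and 0.846 without them. Gpnmb, with a ratio of 2.55 (1.69 to 3.90), was seen in 10 control and 11 photoconversion cells. Bri3bp, Tsc22d1 and Usp18 had ratios of 2.11 (1.49 to 3.02), 2.02 (1.57 to 2.63) and 2.0 (1.32 to 3.06). Among the smallest ratios, the galectin Lgals3 stood at 0.386 (0.307 to 0.483), and at 0.737 without the richest cell of each library, which held 184 of its 346 control UMIs. Stk38 followed with 0.395 (0.242 to 0.624), Gpatch8 with 0.421 (0.279 to 0.621) and Ap3b1 with 0.496 (0.309 to 0.775). When cells were thinned Stk38 (log2 ratio 0.020) and Vhl (0.13) turned in direction. Vhl, Pdcd2l, Golph3, Ciao1, Parp9, Cnot8, Rnf103 and Pdlim4 had ratios from 0.503 to 0.560. With a naming minimum of 200 UMIs, 8 of the 12 largest and 1 of the 12 smallest remained, and with 50 UMIs 6 and 0.

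Cells of other types were few, and their names depended on the clustering. A monocyte-like cluster held 8 control cells (1.44%, 0.624 to 2.82%) and 0 of 317 photoconversion cells, where 3 cells would be a share of 0.946% and the exact upper limit was 1.16%. These values describe the cluster only, since 3 kept photoconversion cells had 3 or more monocyte marker UMIs and microglia-like cells had 0 control and 21 photoconversion UMIs of the monocyte marker Plac8. An endothelial-like cluster held 5.77% of control (3.98 to 8.04%) and 6.62% of photoconversion cells (4.15 to 9.95%). Clustered without marker genes, 9 cells were endothelial-like and 91 astrocyte-like, 50 of them in the control and 41 after photoconversion. In microglia-like sums border macrophage markers had 90 and 19 UMIs, a ratio of 0.277 (0.159 to 0.457), and monocyte markers 24 and 35, a ratio of 1.91 (1.11 to 3.36). Neutrophil markers, nearly all Csf3r, had a ratio of 0.972 (0.833 to 1.13) and neuron markers 1.2 (0.710 to 2.0). Red blood cell genes had 0 and 1 UMIs. List medians were -0.47 (-0.94 to 0.08) for lymphocyte, 0.16 (-0.72 to 0.95) for endothelial and mural, -0.26 (-0.48 to 0.39) for astrocyte and -0.19 (-0.68 to 0.07) for oligodendrocyte markers.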

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

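The clustering on thinned cells and the comparison of neutrophil markers among barcodes of matched depth were fixed before the results were seen. The other tests in this part were chosen afterwards. In barcodes with fewer than 200 genes, which were not among the kept cells of the report, neutrophil markers stood above the control level, at 5303 CPM (4906 to 5724) against 1267 CPM (1091 to 1463). S100a8 had 65 and 238 UMIs there, S100a9 61 and 255, Camp 20 and 96 and Ngp 19 and 55, but Csf3r had 19 and 7, Mmp9 0 and 1, and Retnlg and Cxcr2 0 in both, although the sort excluded Ly6G-positive cells, a gate that would remove neutrophils. The photoconversion library listed shallower barcodes, but among barcodes of at least 62 UMIs 15 of 714 (2.10%, 1.18 to 3.44%) had 3 or more marker UMIs, against 4 of 1340 in the control (0.299%, 0.0814 to 0.763%). Free RNA spread over all barcodes would leave 58.0 to 122 marker UMIs in barcodes with at least 3, whereas 649 of 658 were found in 28 barcodes; the number of such barcodes, looked at first, lay within its simulated range of 17 to 35, and the UMIs they held were chosen as the test afterwards. A candidate explanation is a small number of shallow neutrophils or their fragments after photoconversion, which markers at or near 0 leave uncertain, and the treatment, the mouse pool and the sort cannot be told apart with 1 library per group.

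In the same shallow barcodes oligodendrocyte markers stood at 3990 CPM (3646 to 4357) after photoconversion against 3195 CPM (2912 to 3497) in the control, above the control level, with Mbp at 383 and 363 UMIs, whereas 54 of 1608 photoconversion (3.36%) and 64 of 1340 control barcodes (4.78%) held 3 or more such UMIs.

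The higher MHC class II values did not rest on the richest 10 cells of each library alone, since the list median was 1.27 without them. Nor did they rest on the shares of these states alone. The median was 1.07 with equal weights of states clustered without marker genes and 1.05 with those of planned states. Equal weights do not remove a different mix of cells within a state. The marker-free homeostatic-like state held 13 control and 17 photoconversion cells of the planned disease-associated-like state, at 2701 and 10782 CPM. Earlier tests of free RNA, which compared planned states or assumed an amount of free RNA per droplet, were set aside for the level measured in endothelial-like photoconversion cells, 794 CPM (532 to 1141), where 14 of 29 UMIs were in 1 of 21 cells. Endothelial-like control cells stood at 212 CPM (109 to 370), so class II values were higher after photoconversion in that class too. The test set an excess in microglia-like cells against the whole endothelial-like photoconversion level, not against an endothelial-like excess. The excess over the control level in disease-associated-like cells, 3850 CPM (3663 to 4039), or 3125 CPM (2948 to 3302) in the planned state, lay above that photoconversion level. Their level of 6313 CPM (6156 to 6473) also lay above the 4170 CPM (3784 to 4586) of background barcodes, which free RNA added to the control level would not exceed. In cells homeostatic-like in both clusterings the excess was 477 CPM (335 to 624), within the endothelial-like photoconversion range or below it, so free RNA and expression cannot be told apart there. The endothelial-like class itself depended on the clustering. Without marker genes 9 cells had that name, 3 of them after photoconversion, and 91 were astrocyte-like. For disease-associated-like cells photoconversion, which the values may reflect, stays open beside a difference between the mouse pools or libraries, which is confounded with it.

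The higher disease-associated-like share did not need the marker genes to enter the clustering, since the difference was 11.2 points (5.14 to 17.5) without them. The clusters were still named by those markers, so what the markers contribute to the names was not tested. Depth stays open: clustering on thinned cells gave 4.16 points (-2.63 to 11.1), an interval that holds both 0 and the planned difference of 9.94 points. Disease-associated-like cells were deep, so depth may be a property of the state or may have helped to set it, and these cannot be told apart here. Photoconversion and the mouse pools are confounded here too.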

How the results depend on the processing

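The clusterings without marker genes, the other doublet seed, and the settings by state, with equal state weights or without the richest cells were chosen after seeing the data; the cause of the differences listed here was not tested. No paired analysis was possible because each group had 1 library. The disease-associated-like share was higher after photoconversion in all 10 alternatives that gave it (4.16 to 12.6 points, though intervals of 4.16 on thinned cells and 5.00 with at least 400 genes included 0) and the homeostatic-like share lower in all 11 (-13.5 to -5.35, with 0 inside the intervals without a gene minimum, -12.1 to 0.953, with at least 400 genes, -12.8 to 2.22, and on thinned cells, -13.6 to 1.5); without a gene minimum no disease-associated-like cluster was found. The MHC class II median stayed positive in 25 of 25 alternatives (0.07 to 3.18) and the homeostatic one negative in 25 of 25 (-0.31 to -0.02), while the Trem2-independent, Trem2-dependent and interferon medians kept their direction in 24, 20 and 21. Of the medians of the 5 leading lists, 80 moved less than counting error, 35 more and 10 turned. Of the other list medians, 402 moved less than counting error, 91 more and 5 turned. For the values of named genes these counts were 1468, 246 and 18. A value was counted as turned only where the interval of its main value excluded 0, so more values changed sign than these counts show. The median of mitochondrially encoded genes kept its direction in 10 of 25 alternatives, that of Alzheimer risk gene orthologs in 15 and that of MHC class I genes in 25. The Ccl3 value kept its direction in 7 of 17. Without a gene minimum 1147 control and 1168 photoconversion barcodes were kept, of which 45.6% and 26.4% were microglia-like. The microglia-like shares were 98.3% and 100% with at least 400 genes, 88.2% and 83.9% without a mitochondrial limit, 98.6% and 100% at Leiden resolution 0.4, 100% in both on thinned cells, 88.5% and 86.1% without marker genes, 87.2% and 87.6% with the other doublet seed, and 89.9% in the control at resolution 1.2. With at most 5% mitochondrial UMIs Mt2 turned to 0.082. Scaled without mitochondrial and ribosomal genes, the Trem2-independent median was 0.17. Under TMM the medians were -0.14 for homeostatic, 0.18 for Trem2-independent and 0.0082 for oxidative phosphorylation genes, and C1qa stood at 0.0048; under median-of-ratios scaling they were -0.13, 0.19 and 0.021, with 1.36 for MHC class II and 0.017 for C1qa. With cells weighed equally they were -0.31 for homeostatic, 0.21 for Trem2-independent, 0.37 for Trem2-dependent, 0.64 for MHC class II and 0.031 for oxidative phosphorylation genes, and Bst2 turned to 0.023, Cd2ap to -0.15, Hmox1 to 0.14, Ifi27l2a to 0.086 and Mbp to 0.0065. With cells thinned they were 0.21 for Trem2-independent, 0.0089 for Trem2-dependent, 0.078 for interferon, 0.57 for MHC class II and 0.00069 for glycolysis genes, and Bst2 turned to 0.078, C5ar1 to 0.33, Ccl5 to 0.52, Cd9 to 0.0082, Mt2 to 0.67, Stk38 to 0.020 and Vhl to 0.13. Without the 10 richest cells of each library the interferon median was -0.12 and Hist1h2ap -0.24. In planned disease-associated-like cells the medians were -0.023 for homeostatic, 0.040 for Trem2-independent, -0.013 for Trem2-dependent and 0.52 for interferon genes. In planned homeostatic-like cells they were -0.082 for homeostatic, 0.16 for Trem2-independent, -0.63 for interferon and 1.78 for MHC class II genes. In planned unnamed cells they were 0.10 for Trem2-independent, -0.14 for Trem2-dependent, 0.015 for interferon and 2.54 for MHC class II genes. With equal weights of planned states they were -0.084 for homeostatic, 0.10 for Trem2-independent, -0.043 for Trem2-dependent and -0.056 for interferon genes, with Tmem119 at 0.14 and Trem2 at -0.043. Clustered without marker genes, disease-associated-like cells gave -0.064 for homeostatic, 0.032 for Trem2-independent, -0.085 for Trem2-dependent, 0.46 for interferon and 1.43 for MHC class II genes. Homeostatic-like cells gave 0.33 for Trem2-independent, 3.18 for MHC class II and 0.0017 for lysosomal genes. Unnamed cells gave -0.14 for homeostatic, -0.030 for Trem2-independent, -0.12 for Trem2-dependent, -0.064 for interferon and 0.066 for MHC class II genes. Equal weights of those states gave 0.16 for Trem2-independent and 0.089 for interferon genes. The interferon value in homeostatic-like cells thus turned with the clustering, -0.63 in planned and 0.18 in marker-free states. The naming of genes depended on the UMI minimum: with minimums of 50 and 200 UMIs, 6 and 8 of the 12 largest and 0 and 1 of the 12 smallest ratios stayed among those named.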

Other observations

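Within homeostatic-like cells clustered without marker genes, a comparison chosen after seeing the data, most measured disease-associated genes had higher values after photoconversion. All 8 measured Trem2-independent members were higher, with a median log2 ratio of 0.33, and all 9 measured Trem2-dependent members, with a median of 0.20. In the planned homeostatic-like state these medians were 0.16 and 0.088. Of the other disease-associated genes 12 of 17 were higher and 5 lower without marker genes, with a median of 0.14. The chemokine Ccl3 had a ratio of 0.530 (0.415 to 0.673) and Lgals3, with 14 and 2 UMIs, 0.220 (0.0243 to 0.958). Apoe stood at 2934 and 7249 CPM in homeostatic-like cells of that clustering, a ratio of 2.47 (2.34 to 2.61), against a ratio of 1.11 (1.08 to 1.14) in disease-associated-like cells. The cystatin Cst7 had a ratio of 1.95 (1.71 to 2.23) in homeostatic-like and 0.989 (0.949 to 1.03) in disease-associated-like cells. The planned clustering called 13 of the control and 17 of the photoconversion homeostatic-like cells disease-associated-like, and these held 52566 and 116583 UMIs, against 643730 and 335332 UMIs in the cells called homeostatic-like both ways. With both libraries together, Apoe stood at 2953 and 1500 CPM in the planned homeostatic-like clusters. It stood at 12649 and 43561 CPM in the planned disease-associated-like ones. How far the Apoe and Cst7 ratios rest on the cells that changed state was not tested. In homeostatic-like cells clustered without marker genes cytosolic ribosomal protein genes were higher too, in 78 of 79 members with a median of 0.25. Mitochondrially encoded genes were higher there in 10 of 12 members, with a median of 0.07. Whether the states differed in their ratios was not tested.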
